A study of Ovis aries with 20 samples.

How the data were processed

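Gene expression was measured in the left ventricle (LV) and the interventricular septum of newborn lambs with 20 one-colour (Cy3) Agilent sheep arrays, 5 for each of the groups LV control, LV cortisol, septum control and septum cortisol. Per the labels, total RNA was extracted with Trizol and purified on columns, and 100 ng was amplified and labelled with a low-input kit. Per the file headers, Agilent Feature Extraction 10.1.1.1 scanned each array and made the processed spot intensity by background subtraction with spatial detrending, multiplicative detrending and surrogate values for spots at background. These intensity values were not normalized between arrays. Raw spot and local background intensities were used only for one alternative. The deposited value table holds log2 intensity for 10373 probes, and the submitters' processing notes name limma without a version. The table's medians were 6.71 to 6.72 in LV and 9.49 to 9.54 in septum, so the regions had been normalized separately by a method and background correction that were not stated. Each septum column of that table had 5453 empty cells, and the LV columns had 0. Each of the 20 columns correlated best with its own array (r across probes after centring 0.851 to 0.947; probes are not independent replicates), and 0 columns belonged to other samples. Data from term fetuses of another series were not analysed here.

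The arrays lay on 4 slides. Slide 1 held 6 septum arrays and slide 3 held 6 LV arrays, each with 3 control and 3 cortisol arrays. Slide 2 held 3 LV and 4 septum arrays, and slide 4 held 1 LV cortisol array, that of cortisol 4. Slide 2 held 2 control and 1 cortisol array of LV, and 2 of each in septum. Slide was therefore balanced for treatment in septum but not in LV, and it was largely confounded with region. The share of spots well above background was 57.9% to 72.1% per array, the 75th percentile of the processed signal was 98.4 to 440 intensity units, and 2 to 68 outlier spots per array were left out. The number of arrays limits the precision.

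Of 15008 probes, 1678 (11.2%) could be named, for 1025 genes. Names came from a RefSeq transcript accession (693 probes), a numeric gene identifier (125), a symbol (497), a synonym (20) or the gene description (281), all brought to the symbols of the sheep assembly ARS-UI_Ramb_v3.0, or from the scanner files' own names alone (62). The other 13330 probes, mostly expressed sequence tags, stayed unnamed because no sequence alignment was run. A late batch of 15 description matches was added after some values had been seen. It named COL1A1, COL5A2, COL12A1 and ESR1 among others, and so affects which genes and list members are given.

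Values were log2 of the processed intensity minus the array's 75th percentile, averaged over a probe's spots. Probes entered a test if well above background on at least 5 of the 10 arrays of a region, or on 10 of 20 arrays. Tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all probes tested. Files were read with the R package data.table (version 1.17.8), probes were named in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. The comparisons were cortisol against control in LV and in septum, the cortisol effect averaged over the 2 arrays of each lamb, the difference of the cortisol effect between regions, septum against LV, and the similarity of the 2 regions' cortisol effects. These comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

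Pairing was checked from residuals of each probe within its group. The LV and septum arrays with the same treatment and number correlated at 0.447 to 0.813 across probes, and the own partner was highest in 10 of 10, so they were taken as 1 lamb. Control and cortisol arrays with the same number were not paired. In LV 4 of 5 such pairs exceeded 0.1 (lowest 0.0723), in septum 3 of 5 did (lowest 0.0577), and the own number was highest in 3 of 5 in each region. A replicate block on those numbers was run only as an alternative.

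The named genes were, for each region, the 12 genes with the largest change among those passing or, where none passed, the 12 with the smallest unadjusted p. To these were added the 2 members with the smallest unadjusted p of each list described, and 15 genes chosen for corticosteroid action and heart muscle, where measured. For the other comparisons the rule took up to 10 passing genes, or 5 if none passed. A gene was represented by its probe with the highest mean signal. Some genes that the rule selects are not reported here. Genes outside the rule are said to be chosen after values were seen.

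There were 41 gene lists of heart functions, glucocorticoid responses and cell types. Only a part of each list was measured. In LV, tests used 6 of 87 oxidative phosphorylation genes, 5 of 46 G1/S genes, 5 of 58 actin genes and 7 of 40 glucocorticoid-responsive genes. List values thus describe the measured members, not whole pathways. Some themes of the lists are ones the study is known to have discussed from these samples, so such a list is not independent evidence of its direction. Lists with at least 5 genes measured on every array of the region were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Counts of positive or negative members were not set against the share over all named genes, so a count alone does not mark a list. Alternatives covered quantile normalization, normexp background correction with an offset of 50, the deposited values, filters, array weights, slide and lamb blocks, single slides, a threshold of 0.10, and leaving out each replicate. The fits within single slides, lamb as a random block, lamb as a fixed block combined with other choices, and some list settings were added after seeing the data.

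The fits were tested on simulated data with independent probes, a lamb correlation of 0.6 and 200 changed probes, 100 of each size. In LV 43% of changes of 1 and 87% of changes of 2 on the log2 scale were recovered, with 13 false calls of 143. In septum the shares were 32% and 84% (4 of 120 false), for the averaged effect 53% and 91% (9 of 153), and for the difference between regions 18% and 69% (0 of 87). For septum against LV they were 76% and 96% (0 of 172), and with lamb as block 91% and 99% (13 of 203). A simulated shift of the collagen list by 0.5 was called, with 0 other lists. The simulated genes were independent, whereas the correlation between the real list's genes was estimated at 0.554 in septum. The simulation therefore cannot tell whether camera at the preset correlation is sound for the real list.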

Results

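RNA of the left ventricle (LV) and of the interventricular septum was profiled in 10 newborn lambs, 5 from ewes given cortisol, the main adrenal glucocorticoid, and 5 from ewes given vehicle. The ewes' infusion of 1 mg/kg per day began near gestation day 115 and ran to birth, and hearts were taken between 10 and 480 min after birth. The time for each lamb was not among the labels. Each lamb was taken to give 1 LV and 1 septum array, from their shared deviations, with 57.9% to 72.1% of spots well above background. The median standard deviation within a group was 0.42 in LV and 0.40 in septum on the log2 scale. FKBP5, PER1, TSC22D3 and PDK4, common glucocorticoid targets, and NPPA, NPPB and MYH6, heart muscle genes, could not be named on the array.

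The comparison of cortisol with control LV asks which transcripts of the newborn ventricle differ after raised maternal cortisol. No probe passed the test, so all values here are differences that did not pass. NFIL3, a basic leucine zipper repressor of transcription, had a log2 difference of 1.93 ± 0.47 (SE, n = 5 lambs per group) and IGF1, insulin-like growth factor 1, one of 1.41 ± 0.42, each with 5 of 5 cortisol arrays above the control mean. NFIL3 was well above background on 3 of 5 control arrays, and its difference was 0.56 to 2.25 across alternatives, lowest with normexp background. CALM2, a gene of the calcium sensor calmodulin, stood at 0.99 ± 0.30 and BGN, the matrix proteoglycan biglycan, at 0.64 ± 0.21, also in 5 of 5. TNNC2, troponin C of fast skeletal muscle, was at 2.13 ± 0.73 and INHBA, the activin A subunit, at 1.60 ± 0.62, each in 4 of 5, and INHBA took the other sign in 1 of 26 alternatives. The other 6 of the 12 genes with the smallest p were NUDT16, a nucleotide hydrolase (0.59 ± 0.20), FZD2, a Wnt receptor (0.52 ± 0.18), CLDN3, a tight junction claudin (0.66 ± 0.25), SNRPA, a splicing factor (-0.38 ± 0.14), ITGA4, integrin alpha 4 (-0.66 ± 0.26), and ATP6V1B2, a proton pump subunit (-0.47 ± 0.19). Each of these 6 lay on 1 side of the control mean in 5 of 5 cortisol arrays, though ITGA4 was well above background on 1 of 5. In limma, 0 of 9791 probes passed, 505 had an unadjusted p under 0.05, and all 12 genes had an adjusted p of 0.880. The other settings for the cortisol effect in LV also gave 0, with 221 to 1229 probes under unadjusted 0.05 and a lowest adjusted p of 0.249 to 1.00. Slide 3 alone gave 0 (1119 unadjusted) and slide 2 alone 0 (871).

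The genes of corticosteroid action were measured in LV without a passing difference. NR3C1, the glucocorticoid receptor, had a log2 difference of 0.66 ± 0.28 (SE, n = 5 per group), with 5 of 5 cortisol arrays above the control mean. NR3C2, the mineralocorticoid receptor, stood at 0.03 ± 0.31, with the other sign in 7 of 26 alternatives. HSD11B1, which regenerates active cortisol, was at -0.27 ± 0.33, and HSD11B2, which inactivates it, at 0.98 ± 0.53, well above background on 2 of 5 control and 3 of 5 cortisol arrays. With the chaperone HSP90AA1 as the other member, 4 of 5 genes of this list were positive (list adjusted p = 0.513). Of 7 tested glucocorticoid-responsive genes 5 were positive, such as the metallothionein MT3 (1.29 ± 0.78) and the cell cycle inhibitor CDKN1C (0.55 ± 0.54; list adjusted p = 0.513). MT3 was 0.42 without cortisol 4, whose value lay far above the others, and CDKN1C was 0.24 without cortisol 3, and each took the other sign in 1 of 26 alternatives. HSD11B2 was 0.62 without cortisol 4, whose LV array was the only array on slide 4. In limma, NR3C1 had an adjusted p of 0.880, and its difference was positive in 26 of 26 alternatives.

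The collagen and extracellular matrix genes of LV all had positive differences, 17 of 17, with a median of 0.42 and an adjusted p of 0.0763 that missed the threshold (adjusted p = 0.778 with an estimated correlation). On slide 3 alone the list was positive (adjusted p = 1.01e-05) and on slide 2 alone negative (adjusted p = 0.00591), over a range of 1.47e-06 to 0.778 across alternatives. Slide 2 holds 1 LV cortisol array, that of cortisol 5, so its value rests on 1 lamb assumed to vary like the others. COL1A1, the main fibrillar collagen chain, stood at 0.88 ± 0.45 with 3 of 5 cortisol arrays above the control mean, and COL3A1 at 0.06 ± 0.56, with the other sign in 7 of 26 alternatives. Of 21 genes of BMP, TGF-beta and SMAD signalling 16 were positive, with the signal transducer SMAD2 at 0.46 ± 0.21 (list adjusted p = 0.218). In the list of G1/S and DNA replication 4 of 5 were negative, among them CDK2 (-0.34 ± 0.25) and the replication clamp PCNA (-0.27 ± 0.24; list adjusted p = 0.218). For PCNA, 0 of 1 other tested probes had the same sign. The G2/M cyclin CCNA2 stood at -1.33 ± 0.72 (well above background on 3 of 5 control and 2 of 5 cortisol arrays; -2.15 to -0.31 across alternatives) and HMMR, a spindle protein, at -0.29 ± 0.33, with 4 of 4 members negative. Glycolysis genes were positive in 11 of 12, such as hexokinase HK1 (0.26 ± 0.19) and GAPDH (0.25 ± 0.18; list adjusted p = 0.513). Fatty acid genes were negative in 4 of 7, with CPT1B, the muscle carnitine palmitoyltransferase, at -0.38 ± 0.18 and the carnitine carrier SLC25A20 at -0.29 ± 0.39. Their median was -0.14 and their mean 0.04 (list adjusted p = 0.513), and with normexp background the median was 0.09. Of 6 oxidative phosphorylation genes 4 were negative, with a median of -0.10 and a mean of 0.03 (list adjusted p = 0.585), though the ATP synthase genes ATP5MC2 (0.50 ± 0.26) and ATP5PO (0.52 ± 0.30) were positive. Actin cytoskeleton genes were positive in 4 of 5, such as ACTG1 (0.32 ± 0.25) and the GTPase RAC1 (0.21 ± 0.18; list adjusted p = 0.585).

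Some LV lists had too few measured genes for a list test. The calcium handling members included RCAN1, a calcineurin inhibitor (-0.37 ± 0.64), and the ion channel and gap junction members GJA1, connexin 43 (-0.18 ± 0.30), and ATP1B1, a sodium pump subunit (-0.06 ± 0.21). Of the other tested probes, 0 of 3 for GJA1 and 0 of 1 for ATP1B1 had the same sign, so neither direction is settled. For ATP1B1, 4 of 5 cortisol arrays lay above the control mean despite the negative difference. The sarcomere genes MYH7, the slow myosin heavy chain, and TPM1, tropomyosin 1, stood at 0.41 ± 0.31 and 0.63 ± 0.53, and TPM1 had values on only 3 control and 2 cortisol arrays, since outlier spots were left out, and was -0.24 without cortisol 4. IDH1, an isocitrate dehydrogenase, was at 0.58 ± 0.31. Among markers of other cells, haemoglobin HBB was at 0.06 ± 0.49, with the other sign in 12 of 26 alternatives. The monocyte genes CD14 and CD86 were at 0.50 ± 0.47 and 0.38 ± 0.45 (list adjusted p = 0.591), the T cell genes CD3D and CD3E at -0.52 ± 0.62 and 0.03 ± 0.61 (CD3D well above background on 3 of 5 cortisol arrays), and the neutrophil cathelicidin BAC5 at -0.61 ± 1.49, which was 0.54 without control 2. RCAN1 was 0.02 without cortisol 4. Camera called 0 of 24 lists in LV, fry called 0, and 0 list members passed when adjusted over the list alone.

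**Figure D1:**
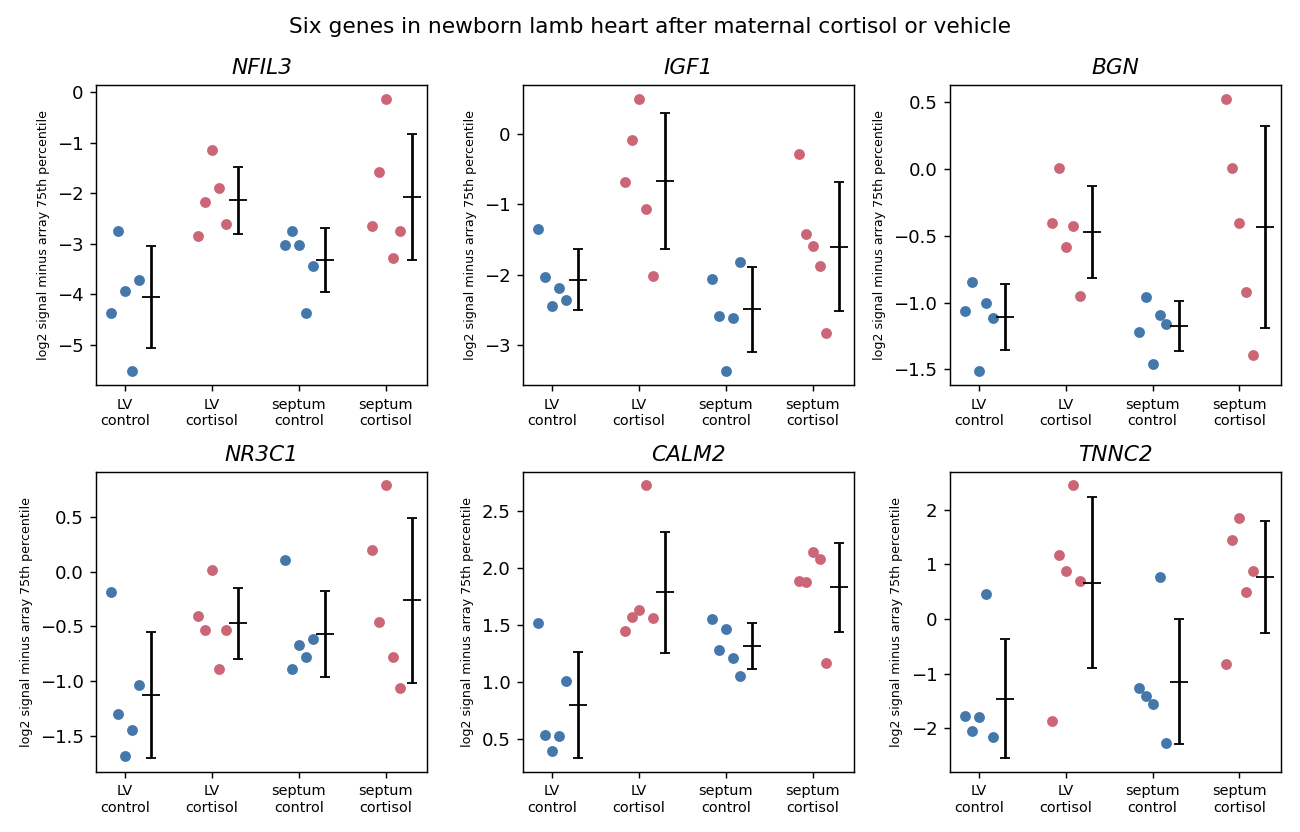
Each point is 1 array of a newborn lamb (n = 5 per group), with log2 signal minus the array's 75th percentile on the vertical axis and the 4 groups along the horizontal axis; black marks show the group mean and standard deviation. NFIL3 averaged -4.06 in control LV and -2.13 in cortisol LV, and none of the differences shown passed the test in limma.

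The comparison of cortisol with control septum asks the same of the wall between the ventricles. No single probe passed. The collagen and extracellular matrix genes passed as a group with camera at its preset correlation (adjusted p = 0.0105), but not otherwise (adjusted p = 0.725 with an estimated correlation; fry adjusted p = 0.502), and other groupings of the lambs did not exclude chance. All 17 of 17 measured members had positive differences, with a median of 0.46 and a mean of 0.505 on the log2 scale (n = 5 lambs per group). COL1A1 stood at 0.92 ± 0.44, the matrix proteoglycan BGN at 0.74 ± 0.32 and COL3A1 at 0.22 ± 0.43, and none of the 17 passed as a single gene. Among individual cortisol lambs, the list mean relative to the region mean was 0.82, 0.68 and 0.66 in cortisol 1, 2 and 3 and -0.38 and -0.51 in cortisol 4 and 5, against -0.34 to -0.11 in control lambs. Fibroblast markers were positive in 7 of 7 (adjusted p = 0.143), but 5 of the 7 are members of the collagen list. Without septum control 1, cortisol 1 or cortisol 3 the adjusted p of the camera test was 0.0540, 0.0957 or 0.0506. On slide 1 alone the list had an adjusted p of 6.98e-06, and on slide 2 alone it went the other way (adjusted p = 0.125), over a range of 6.98e-06 to 0.725 across alternatives. Slide 1 held the septum arrays of cortisol 1, 2 and 3, and slide 2 those of cortisol 4 and 5. Leaving out a lamb moved the list mean between 0.364 (without cortisol 1) and 0.697 (without cortisol 5).

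**Figure D2:**
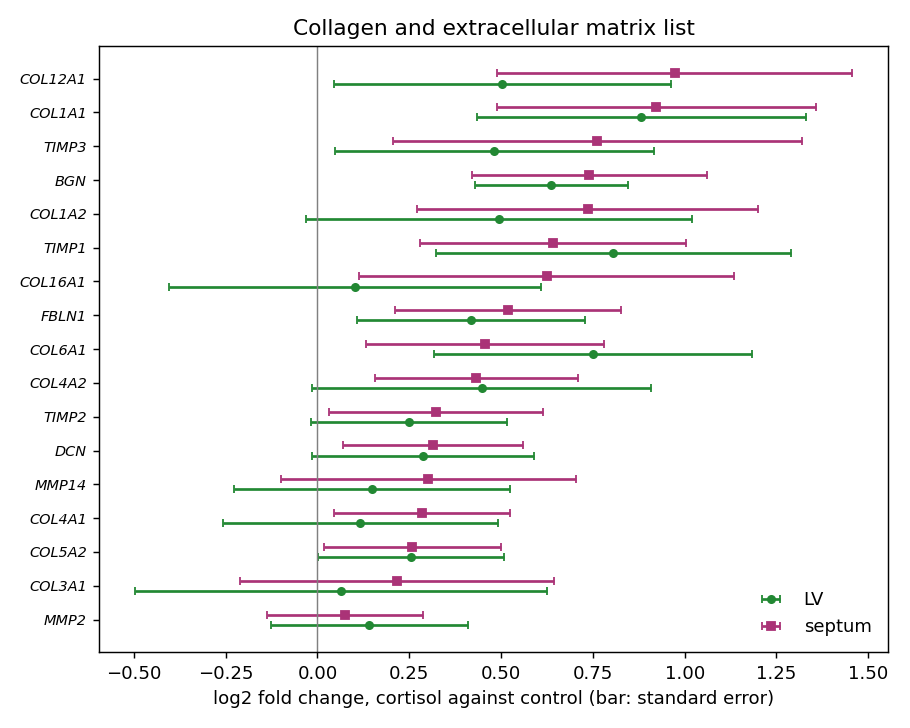
The log2 fold change of cortisol against control (horizontal axis, bars are standard errors, n = 5 lambs per group) is shown for the 17 collagen and extracellular matrix genes in LV and septum. All 17 values lie above 0 in each region, with medians of 0.42 in LV and 0.46 in septum.

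Single genes of the septum did not pass. APOA1, the main apolipoprotein of high-density lipoprotein, had a log2 difference of 0.75 ± 0.20 (SE, n = 5 lambs per group) and FAS, a death receptor, one of 0.88 ± 0.27, each in 5 of 5 cortisol arrays. TNNC2 stood at 1.91 ± 0.60, in 5 of 5, and CALM2 at 0.52 ± 0.21, in 4 of 5. AANAT, an enzyme of melatonin synthesis, was at 0.60 ± 0.23, the hormone gene PRLH at 0.69 ± 0.27 and the mitochondrial carrier SFXN1 at 0.54 ± 0.22. The negative values were those of IRF3, an interferon regulatory factor (-0.46 ± 0.16), OVAR-DQA1, a class II histocompatibility gene (-0.67 ± 0.28), CYP2J, a cytochrome P450 (-1.16 ± 0.42), and the ADP-ribosyltransferase ART4 (-0.83 ± 0.33). CYP2J was well above background on 2 of 5 and ART4 on 1 of 5 cortisol arrays, so these differences are against a group near background, and each took the other sign in 1 of 24 alternatives. In limma, 0 of 10369 probes passed, 384 had an unadjusted p under 0.05, and the genes named here had an adjusted p of 0.818. The other settings for the cortisol effect in septum also gave 0, with 7 to 1817 probes under unadjusted 0.05 and a lowest adjusted p of 0.0551 to 1.00. Slide 1 alone gave 0 (1721 unadjusted) and slide 2 alone 0 (318).

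In septum the glucocorticoid receptor NR3C1 stood at 0.31 ± 0.34 (SE, n = 5 per group), with 3 of 5 cortisol arrays above the control mean and the other sign in 1 of 26 alternatives, and NR3C2 at -0.04 ± 0.21. HSD11B1 was at -0.58 ± 0.34, below the control mean in 5 of 5, and HSD11B2 at 0.20 ± 0.77, well above background on 3 of 5 arrays of each group. The receptor list had 3 of 5 members positive and a median of 0.14, while camera placed it lower than other genes (adjusted p = 0.425). Glucocorticoid-responsive genes were positive in 7 of 8, such as MT3 (0.62 ± 0.35) and RGS2, a regulator of G protein signalling (0.48 ± 0.50; list adjusted p = 0.425). Such a count was not particular to this list. Genes of mitochondrial biogenesis and nuclear receptors were also positive in 7 of 8, yet camera placed them lower than other genes (adjusted p = 0.976). Without cortisol 3, RGS2 was 0.07 and NR3C1 0.04. The G1/S list was negative in 4 of 6, with CDK2 at -0.43 ± 0.24 and cyclin CCND3 at -0.29 ± 0.27 (list adjusted p = 0.0965). The G2/M list was negative in 3 of 6, with CCNA2 at -1.15 ± 0.58 (well above background on 3 of 5 cortisol arrays; -1.44 to -0.12 across alternatives) and the mitotic kinase CDK1 at -0.72 ± 0.47 (list adjusted p = 0.0993), and its median of -0.22 turned to 0.02 with normexp background. BMP, TGF-beta and SMAD genes were positive in 16 of 22, with INHBA at 1.34 ± 0.58 and SMAD1, well above background on 2 of 5 control and 3 of 5 cortisol arrays, at 0.85 ± 0.41 (list adjusted p = 0.330). Glycolysis genes were positive in 11 of 12, with GAPDH at 0.29 ± 0.18 and HK1 at 0.37 ± 0.24 (list adjusted p = 0.323).

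Fatty acid genes of the septum were negative in 4 of 6, with CPT1B at -0.26 ± 0.18 and SLC25A20 at -0.31 ± 0.37 (list adjusted p = 0.148), and their median of -0.21 turned to 0.05 with normexp background. Oxidative phosphorylation genes were positive in 5 of 6, with ATP5MC2 at 0.42 ± 0.21 and ATP5PO at 0.33 ± 0.22 (list adjusted p = 0.425), and in 3 of 6 after quantile normalization. Actin genes were positive in 4 of 5, with the actin-severing protein CFL1 at 0.41 ± 0.23 and ACTG1 at 0.47 ± 0.30 (list adjusted p = 0.330). Of the small lists, PRKACA, the protein kinase A catalytic subunit, was at 0.25 ± 0.19, ATP1B1 at 0.10 ± 0.16, TPM1 at 0.39 ± 0.21, the chaperone CRYAB at 0.39 ± 0.24, MYH7 at 0.26 ± 0.29 and IDH1 at 0.00 ± 0.76. The red cell genes HBB and AHSP stood at 0.36 ± 0.57 and 0.06 ± 1.09 (AHSP well above background on 3 of 5 arrays of each group), the myeloid genes TYROBP and CD14 at 0.59 ± 0.25 and 0.33 ± 0.38 (list adjusted p = 0.425), CD3D and CD3E at 0.49 ± 0.72 and 0.42 ± 0.72, and BAC5 at -0.27 ± 1.59. Without cortisol 3, HBB was 0.01, and without control 5, CD3D was -0.13 and CD3E -0.11. Camera called 1 of 24 lists in septum, fry and the estimated correlation called 0, and 0 list members passed when adjusted over the list alone.

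Averaging the 2 arrays of each lamb asks for a cortisol effect on the mean of both walls. A change in 1 wall alone can also move that mean, so a shared effect is not tested by it. CALM2 had a log2 difference of 0.76 ± 0.21, FAS of 0.89 ± 0.25, NFIL3 of 1.59 ± 0.47, ESR1, an oestrogen receptor, of 0.90 ± 0.27 and TNNC2 of 2.02 ± 0.62 (SE, n = 5 lambs per group), and none passed (adjusted p = 0.815 in limma). The collagen list had an adjusted p of 0.0114 with camera in this comparison, which was lost in other list tests (adjusted p = 0.776 with an estimated correlation; fry adjusted p = 0.619). In limma 0 of 10069 probes passed, and 519 had an unadjusted p under 0.05. With slide as a fixed block 4 of 10069 passed, 2 higher and 2 lower, among them PYGL, liver glycogen phosphorylase (0.64, chosen after its value was seen), and 3 unnamed probes. The other settings for the cortisol effect averaged over both regions gave 0, with 55 to 1551 unadjusted and a lowest adjusted p of 0.127 to 1.00.

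The difference of the cortisol effect between regions was tested directly, with septum minus LV as the direction. Unless a lamb block is named, the fit took the 20 arrays as independent and left out the pairing by lamb. ITGA4 had a difference of 1.01 ± 0.34, SNRPA of 0.50 ± 0.23, AQP8, a water channel, of 0.39 ± 0.23, UBB, polyubiquitin B, of 0.68 ± 0.41 and CYP2J of -1.01 ± 0.63 (log2 and SE, n = 5 lambs per group), with adjusted p of 1.00 in limma. ITGA4 and CYP2J were each well above background on 2 of 5 septum cortisol arrays, and UBB had values on only 2 control and 2 cortisol LV arrays, since outlier spots were left out. Of 10069 probes 0 passed and 38 had an unadjusted p under 0.05. With lamb as a block 0 passed (362 unadjusted), and all settings for the difference of the cortisol effect between regions gave 0, with 0 to 550 unadjusted and a lowest adjusted p of 0.283 to 1.00. No gene was therefore shown to respond differently in the 2 walls, and lists were not tested for this difference.

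The 2 regions' cortisol effects had a Pearson correlation of 0.729 and a Spearman correlation of 0.707 over 10069 probes, which are not independent replicates, and 76.6% of probes had the same sign. The regions came from the same lambs. Where each region's effect was taken from other lambs than the other region's, the median correlation of 100 such choices was 0.0507 (-0.272 to 0.304), and 36 of 100 were below 0. Each effect there rested on fewer lambs than the 5 per group behind 0.729, which lowers a correlation by itself. How much of the fall came from the shared lambs therefore cannot be told. Other groupings of the same lambs gave a median Pearson correlation of 0.676 (0.480 to 0.830), with both arrays of a lamb kept together. A correlation near 0.729 thus arose without the treatment grouping, so it is not evidence of a shared cortisol response.

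**Figure D3:**
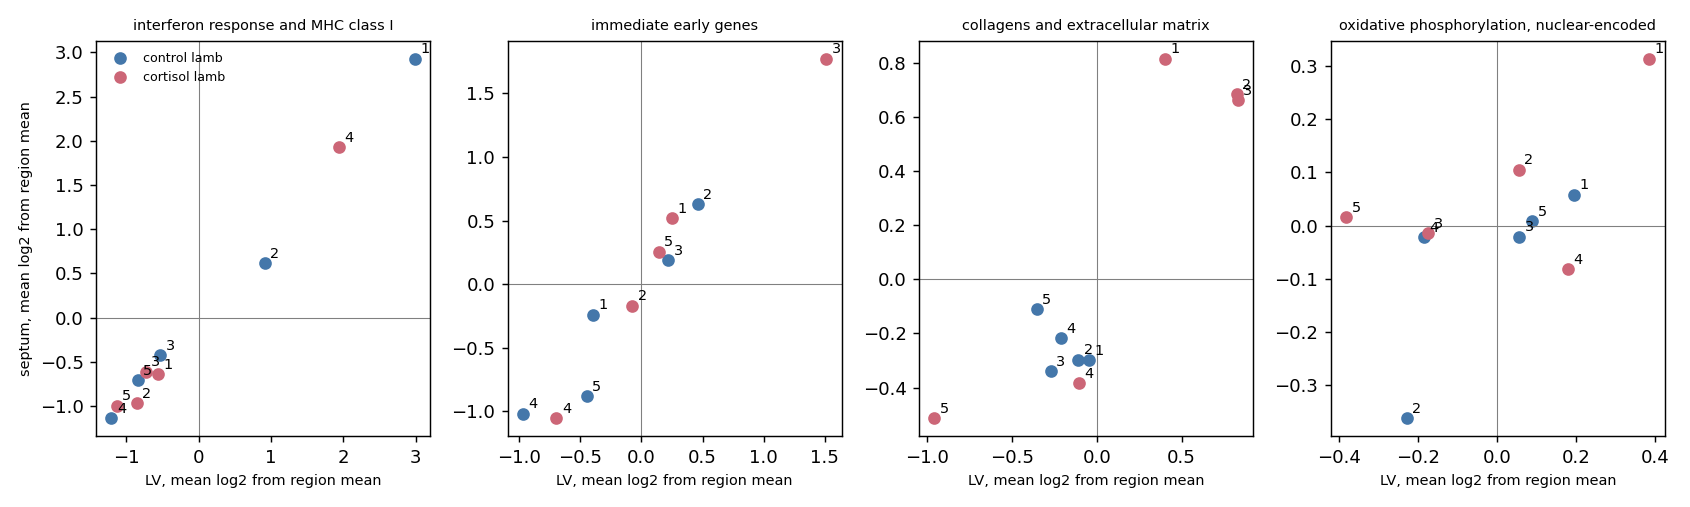
Each point is 1 lamb, numbered within its treatment (n = 5 per treatment), and the axes give the mean log2 value of a gene list relative to the region mean, LV on the horizontal and septum on the vertical axis. The interferon list stood at 2.99 and 2.93 in the LV and septum of control 1, and the collagen list was highest in cortisol 1, 2 and 3.

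Septum against LV asks how the 2 walls differ whatever the treatment. The fit given first took the 20 arrays as independent and left out that 2 came from each lamb. Most probes that passed in this fit were lower in septum. ITGB6, the beta 6 subunit of an integrin that activates TGF-beta, was lower in septum, with a log2 difference of -1.42 ± 0.28 (SE of this fit, 10 lambs). HAND1, a transcription factor of left ventricular development, had one of -1.41 ± 0.30, and both genes were lower in 10 of 10 lambs. With lamb as a block the SE was 0.12 for ITGB6 and 0.13 for HAND1. Differences were -1.04 ± 0.23 for COL4A1, a basement membrane collagen, -0.87 ± 0.18 for FGF7, a fibroblast growth factor, and -0.69 ± 0.14 for GLUD1, mitochondrial glutamate dehydrogenase, also in 10 of 10. ITGA4 had a difference of -0.79 ± 0.17, lower in 9 of 10 lambs, and was well above background on only 5 LV control, 1 LV cortisol, 4 septum control and 2 septum cortisol arrays. In ARS-UI_Ramb_v3.0, ITGB6 lies on chromosome 2 from 149499147 to 149642596 and HAND1 on chromosome 5 from 63540026 to 63543335. COL4A1 lies on chromosome 10 from 84241592 to 84369833, FGF7 on chromosome 7 from 58927837 to 58990908, GLUD1 on chromosome 25 from 40640653 to 40679694 and ITGA4 on chromosome 2 from 128281242 to 128376483. Among unnamed probes, A_70_P035166 had a difference of -3.53 and was lower in 10 of 10 lambs, and A_70_P034846 had one of 2.16 and was higher in 10 of 10. In limma 55 of 10069 probes passed, 51 lower and 4 higher in septum, and the adjusted p was 0.0307 for ITGB6, 0.0441 for HAND1 and ITGA4, 0.0472 for COL4A1, 0.0411 for FGF7 and 0.0336 for GLUD1. With slide as a fixed block 0 passed for septum against LV (611 unadjusted), and slide 2 alone gave 0 (693 unadjusted). With normexp background 1 passed, the unnamed A_70_P034846, and none of the 6 named genes. Leaving out 1 array gave 9 (without septum control 4) to 424 (without LV cortisol 5). In the 3 lambs with both arrays on slide 2 the means were -1.61 for ITGB6, -1.28 for HAND1, -0.79 for COL4A1, -0.76 for FGF7, -0.65 for GLUD1 and -0.84 for ITGA4, lower in 3 of 3.

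**Figure D4:**
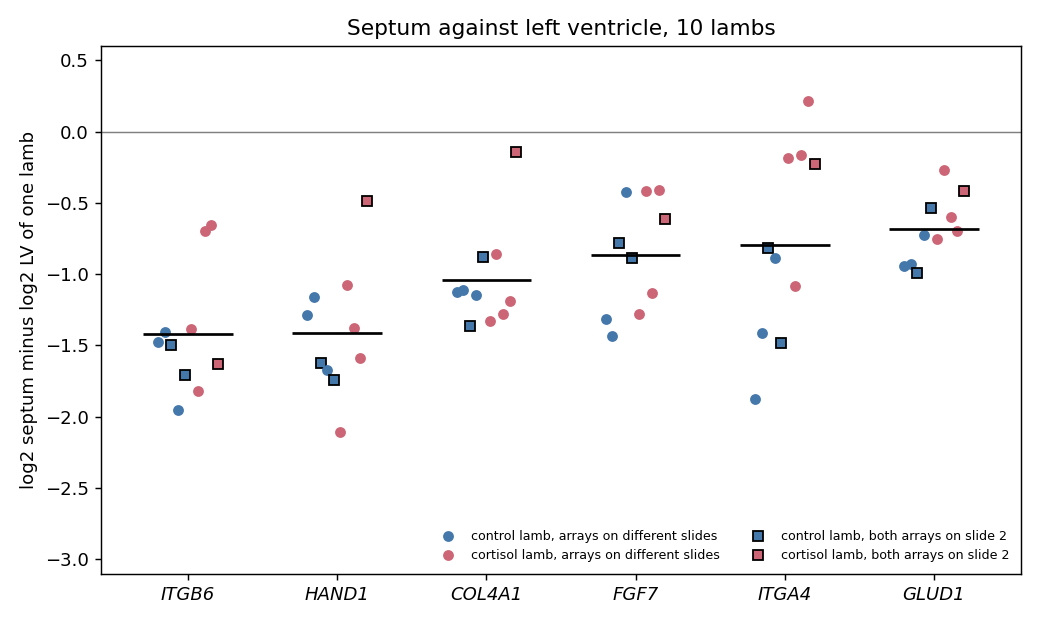
The vertical axis gives the log2 difference of septum minus LV within a lamb for the 6 named genes that passed; each point is 1 of 10 lambs, squares mark lambs with both arrays on slide 2, and black lines are means. All lambs lie below 0 except 1 for ITGA4.

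With lamb as a block, 1770 probes passed for septum against LV, 749 higher and 1021 lower in septum, but only 8 passed with the same block and normexp background. Among named genes 136 of 649 passed, 54 higher and 82 lower. The genes given next were chosen after their values were seen. Higher in septum were CD93, a receptor of endothelial and myeloid cells (0.75 ± 0.13), IGFBP2, a binding protein of insulin-like growth factors (0.57 ± 0.10), the lysosomal lipase LIPA (0.43 ± 0.07) and IGF2R, the mannose 6-phosphate receptor (0.42 ± 0.07), each in 10 of 10 lambs (log2 and SE, n = 10). Lower in septum were the fibrillar collagens COL3A1 (-1.36 ± 0.15) and COL1A2 (-1.12 ± 0.13), the basement membrane collagen COL4A2 (-1.09 ± 0.14), the kinase PIM1 (-1.29 ± 0.17) and CPT1A, a carnitine palmitoyltransferase (-1.16 ± 0.13), each in 10 of 10. FABP4, the fatty acid binding protein of adipocytes and capillaries, was lower in 9 of 10 lambs (-2.29 ± 0.54), but it was well above background on only 10 of 20 arrays, so the size of its difference is uncertain. Of the collagen and extracellular matrix list 14 of 17 were lower in septum, with a median of -0.22 (camera adjusted p = 0.0910; adjusted p = 0.995 with an estimated correlation; fry adjusted p = 0.942). With lamb as block, fry gave this list an adjusted p of 0.0239, while camera gave 0.152 and did not pass (adjusted p = 0.949 with an estimated correlation). Fry with lamb as block also called renin-angiotensin and adrenergic receptors (adjusted p = 0.00155), fibroblast markers (0.0248), immediate early genes (0.0470) and macrophage and monocyte markers (0.0490), all as lower in septum. Camera with lamb as block gave each of these 4 lists an adjusted p of 0.709 (adjusted p = 0.949 with an estimated correlation). The fibroblast markers that passed were COL3A1, COL1A2 and COL1A1, which are also in the collagen list. The fibroblast markers VIM (0.04), DCN (-0.04), FBLN1 (0.21) and S100A4 (0.73) did not pass. With lamb and slide both as fixed blocks 0 probes passed for septum against LV (1707 unadjusted, lowest adjusted p 0.0564, over a range of 1.94e-06 to 0.671 across alternatives). In that fit the differences were -1.58 ± 0.21 for ITGB6, -1.24 ± 0.26 for HAND1 and -0.75 ± 0.19 for COL4A1. They were -0.74 ± 0.22 for FGF7, -0.69 ± 0.24 for ITGA4 and -0.59 ± 0.13 for GLUD1.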

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

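Tests chosen only after the result was seen were those of other groupings for the cortisol comparisons, the similarity and the LV lists, of slide for septum against LV, the collagen list and the lamb pairs, and of brightness and fibroblasts for the collagen list. Of 230 groups of named genes and array measures tested, 14 held 1 array far from the others, against 11.5 expected by chance at 1 in 20.

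In LV, CALM2 was 2.73 in cortisol 4 against 1.45 to 1.63 in the other 4 (log2 signal; gap over range 0.854). MT3 was 4.42 in cortisol 4 against -0.71 to 0.73 (0.719), and ATP1B1 was 5.69 there against 6.43 to 6.73 (0.712). The LV array of cortisol 4 was the only array on slide 4. Its 75th percentile was 400 intensity units, against 98.4 to 271 on the other LV arrays. Its deviations therefore cannot be told apart from slide or brightness. TNNC2 was 0.46 in control 4 against -2.15 to -1.77 (0.855), and NUDT16 was -0.83 in control 3 against -0.24 to -0.07 (0.773). ATP1B1 was 6.69 in control 1 against 6.26 to 6.38 (0.711), HBB was 5.49 in control 2 against 3.03 to 3.66 (0.745), and FGF7 was 2.22 in cortisol 1 against 0.88 to 1.16 (0.795). In septum, INHBA was -3.56 in cortisol 5 against -0.87 to -0.59 (0.904), and CALM2 was 1.17 there against 1.88 to 2.14 (0.727). GAPDH was 6.43 in cortisol 4 against 6.86 to 6.97 (0.800). NR3C1 was 0.11 in control 1 against -0.89 to -0.61 (0.720), and NR3C2 was 3.02 there against 2.13 to 2.35 (0.749), and CD3D was -6.79 in control 5 against -4.31 to -3.38 (0.727). No explanation was tested for these arrays.

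Other groupings of the same lambs were counted, the real one included. Where the real count was 0, all 100 of 100 splits reach it by construction, so these counts decide nothing; the highest other split called 3 probes in LV, 36 in septum, 178 for the averaged effect and 1 for the difference between regions. At unadjusted p under 0.05, 40 of 100 splits had as many probes as the real 505 in LV (highest other 1812) and 50 as many as the real 384 in septum (highest other 2545). For the averaged effect 38 had as many as the real 519 (highest other 2389), and for the difference between regions 64 as many as the real 38 (highest other 157), so chance could not be excluded for any of the 4. With slide as a fixed block for the averaged effect, 11 splits called as many as the real 4, and the highest other called 519. The many probes called by some septum and averaged splits may point to a structure of the samples other than treatment, or to correlated probes, which was not tested. For the similarity of the regions, 25 splits reached the real 0.729, with a highest other of 0.830. Chance could not be excluded for the slide-blocked count or the similarity. For the lists in septum, 86 splits called at least the real 1 (highest other 8), so chance could not be excluded. In LV the real count was 0, which 100 of 100 splits reach by construction, and the highest other was 7.

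For septum against LV, chance alone was argued against, though not excluded. Region was exchanged within some of the lambs, and 2 of 100 splits called as many probes as the real 55, the real one included, with a highest other of 122. With lamb as block 1 of 100, the real one, reached 1770, with a highest other of 1618. In 7 lambs the 2 arrays lay on different slides. Exchanging region there also exchanged slide, so these counts cannot tell region from slide.

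The first pattern weighed was septum against LV, for which a slide offset as the whole cause was argued against by the lambs with both arrays on slide 2, where 87.4% of the 920 probes called in the other 7 lambs moved the same way (69.5% of all probes). Their median size was 0.33 there against 0.58 in the 7 lambs, so a part due to slide stays open. At equal array brightness the difference was 100.6% of the mean difference (0.46, 95% interval 0.34 to 0.58). This value cannot decide on brightness, since it used only probes called with lamb as block in these same lambs. Such probes were selected for a steady difference across lambs. Septum was the brighter array in 9 of 10 lambs, so a part due to brightness stays open. With slide as a block the errors of all named genes that had passed grew, and their calls ended. ITGB6 went from -1.42 ± 0.28 to -1.41 ± 0.46, HAND1 from -1.41 to -1.50 and GLUD1 from -0.69 to -0.81. The difference shrank for COL4A1, from -1.04 ± 0.23 to -0.75 ± 0.36, for FGF7, from -0.87 to -0.69, and most for ITGA4, from -0.79 ± 0.17 to -0.48 ± 0.28. A difference between the tissues may underlie part of the pattern, as a hypothesis.

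A further pattern was the collagen list in septum, higher in cortisol lambs 1 to 3 and not in cortisol 4 and 5. Chance could not be excluded, since 14 of 100 splits gave this list a p as small as the real 0.000436, the smallest other being 6.71e-09, and 12 of the 14 kept cortisol 1 to 3 together. A common slide offset was argued against, since slides 1 and 2 differed by -0.05 in control lambs (95% interval -0.34 to 0.25) and by 1.17 in cortisol lambs (0.92 to 1.42), a share of -3.97%. In septum, cortisol 1 to 3 lay on slide 1 and cortisol 4 and 5 on slide 2, so the 1.17 restates the pattern already seen. A slide effect confined to the cortisol arrays cannot be told apart from it. Brightness accounted for 5.66% of the list mean (95% interval -43.3% to 54.6%), which leaves a share of it open. A larger share of fibroblasts could not be told apart, because S100A4 (0.34 ± 0.95) and VIM (0.47 ± 0.33) were too uncertain beside the list median of 0.46, and a cortisol effect in some lambs or a handling batch of particular lambs may also contribute.

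The last pattern was that LV and septum arrays of the same treatment and number deviated from their groups together. Their median correlation was 0.677 across probes, which are not independent replicates. These same correlations were the ground for taking such arrays as 1 lamb, so they are not independent evidence of differences between lambs. Slide was argued against as the whole cause, since the 7 pairs on different slides correlated at 0.447 or more. Brightness was argued against as the whole cause, since the median was 0.558 with brightness regressed out. Differences between lambs, such as the time from birth to collection, may explain it, but the labels give no group for this and no biological explanation was tested. Shared handling of a lamb's samples stays open.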

How the results depend on the processing

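Tests chosen only after the data were seen were the fits within single slides, lamb as a random block, lamb combined with leaving out lambs, scaling or slide, and the lists with slide, replicate block or normexp background. The cause of each difference given here was not tested unless stated.

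The cortisol effect in LV, the cortisol effect in septum and the difference of the cortisol effect between regions gave 0 probes in limma under every alternative run. With the replicate block the cortisol effect in LV had 606 and the cortisol effect in septum 678 probes at unadjusted p under 0.05. The cortisol effect averaged over both regions gave 4 with slide as a fixed block and 0 otherwise. The deposited value table was not used for the averaged effect, the difference between regions or septum against LV, since its regions were normalized separately. Of the values for named genes under alternatives, 2710 kept sign and side of the threshold, 133 for septum against LV kept only the sign, and 129 for cortisol took the other sign.

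For septum against LV, against 55 as reported, the count was 1 with normexp background, 139 with normexp and quantile normalization, 118 with no filter on dim probes, 338 with array weights and 162 at adjusted p under 0.10. It was 0 with slide as a fixed block (611 unadjusted), 2 with slide as a random block, and 281 with slide as a fixed and lamb as a random block. It was 1770 with lamb as a fixed block, 2065 with lamb as a random block, and 0 with lamb and slide both fixed (1707 unadjusted). Slide 2 alone gave 0 (693 unadjusted), and 0 with the lamb block (1432 unadjusted), from fewer arrays. Leaving out 1 array gave 9 (without septum control 4) to 424 (without LV cortisol 5). With the lamb block the count was 1832 after quantile normalization, 8 with normexp and 2104 with normexp and quantile normalization. Leaving out both arrays of control 1 to 5 gave 1109, 1184, 1142, 1194 and 1186, and of cortisol 1 to 5 gave 1422, 1527, 1519, 1704 and 2291. ITGB6 passed in 35 of 49 alternatives (-1.62 to -0.97), HAND1 in 27, COL4A1 in 24, FGF7 in 26 and GLUD1 in 29 of 49, and ITGA4 in 19 of 48, all with a negative sign.

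The similarity of the regions was 0.0507 with each region from other, and fewer, lambs. It was 0.627 (without cortisol 3) to 0.787 (without cortisol 5) when a lamb was left out.

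The lists in LV, with 0 called as reported, gave 1 with quantile normalization, 1 with slide as a fixed block, 1 with the replicate block, 5 on slide 3 alone, 1 on slide 2 alone, and 0 to 2 (2 without control 4) when an array was left out. The lists in septum, with 1 called, gave 0 with an estimated correlation, 0 with fry, 0 with the replicate block, 2 with normexp, 4 on slide 1 alone, and 0 (without control 1) to 4 (without control 3) when an array was left out. On slide 2 alone the collagen list was negative in LV (adjusted p = 0.00591) and septum (0.125), and the hypoxia list was negative in septum (0.0357). The range over alternatives was 1.47e-06 to 0.778 for LV collagens and 6.98e-06 to 0.725 for septum collagens. Slide 2 alone has 2 control arrays and 1 cortisol array in LV, so the lone array is assumed to vary like the others.

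Signal over background limited dim genes such as ITGA4. Without a filter the median of all probes stood at 0.13 in septum and 0.11 for the averaged effect, and the other scalings moved it by under 0.1.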

Other observations

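The genes and lists here were chosen only after their values were seen, and no tests were run on the differences between single lambs. As groups of cortisol against control, the interferon list (adjusted p = 0.218 in LV, 0.0965 in septum), the hypoxia list (0.218 and 0.425) and the immediate early, inflammatory and glucocorticoid-responsive lists (0.513 and 0.425 each) did not pass with camera. The interferon list passed in 4 of 19 LV and 6 of 19 septum alternatives, over a range of 0.00475 to 0.957 in LV and 0.00253 to 0.731 in septum. The interferon list had its highest mean in control 1, 2.99 in LV and 2.93 in septum above the region mean (log2), with cortisol 4 next at 1.94 and 1.93. ISG15, an interferon-induced ubiquitin-like protein, ranged from -3.95 to 4.32 over the 20 arrays and was highest in control 1, as was MX1, an antiviral GTPase (-3.29 to 3.58). The immediate early, hypoxia and inflammatory lists were highest in cortisol 3, at 1.51, 1.17 and 1.66 in LV and 1.77, 1.54 and 1.34 in septum. FOS, an immediate early transcription factor, ranged from -4.37 to 2.70 and CXCL8, a neutrophil chemokine, from -6.10 to 2.08, both highest in cortisol 3. CXCL8 was well above background on 16 of 20 arrays, and its lower end is a background value. The glucocorticoid-responsive list was also highest in cortisol 3 (0.95 in LV and 0.81 in septum). CATHL3, a neutrophil cathelicidin, ranged from -6.96 to 2.09, and fetal haemoglobin HBBF from -5.97 to 1.69, both highest in control 2. CATHL3 was well above background on 14 and HBBF on 18 of 20 arrays, and their lower ends are background values. PPARGC1A, a coactivator of mitochondrial biogenesis, ranged from 0.16 to 4.91.

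CLDN3, the tight junction claudin, stood at 7.16 in septum control 4, against -2.41 to -2.05 in the other septum controls and -2.32 in the LV of that lamb. RPS25, a ribosomal protein gene, was well above background on 5 of 5 septum control arrays and on 0 of 5 septum cortisol arrays. The lowest log2 signal called well above background was -5.72 to -5.04 in septum control and -4.93 to -4.44 in septum cortisol arrays. Detection thus differed between the groups, and RPS25 averaged -4.65 in control. The lower bound on its difference was 1.06-fold (0.09 on the log2 scale), small beside a control standard deviation of 0.38, and was not tested.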
